A study of Homo sapiens with 12 samples.

How the data were processed

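RNA of 12 cultures of 2 esophageal carcinoma cell lines, OE21 (squamous cell carcinoma) and OE33 (Barrett's adenocarcinoma), was measured on Illumina expression BeadChips. Each line was transfected with a STAT3 siRNA pool or with a negative control siRNA, giving 4 groups of 3 arrays. Per the labels' protocols, the pool held 4 sequences and was given at 100 nM in 2 transfections, and RNA was taken 72 h after the first. OE33 was transfected with DharmaFECT and OE21 with siPORT NeoFX, so cell line and reagent cannot be told apart. The design text calls the 3 replicates of a group independent experiments. All 12 arrays carry 1 array identifier in the labels, so no slide batch could be tested. Untreated cells named in the protocol are not analysed here.

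Per the labels' protocols, RNA was extracted with RNeasy Plus columns, checked on a Bioanalyser and turned into biotinylated cRNA with a MessageAmp kit. The authors deposited a table of probe intensity per array on the linear scale, not normalised between arrays, and beside each intensity a detection p-value. How the detection p-value was computed, and the scanner software, are not given in the sources used here. The authors also deposited normalised intensity values. Set against the first table, each array's normalised column followed its own array (Spearman correlation across probes of at least 0.99996), on a linear scale, not centred. Their medians lay between 106.4 and 107.2 on all arrays, and the method that gave them is not given in the sources used here. They served as an alternative.

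Of 47323 probes, 4 with a missing value were left out. Between 18034 and 19149 probes per array were detected. The platform annotation gave 30111 probes 1 gene symbol, 8 probes several and 17200 none. Entrez identifiers of 30072 probes matched the GRCh38.p14 gene table, which changed 0 symbols. Gene names came only from probes with 1 symbol, and probes without a symbol are unnamed here. The lists of genes were fixed before the data were examined, as were the groups, the tests, the rule for named genes and all alternatives except those said to be added later.

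Intensities of all 12 arrays were background-corrected and quantile-normalised with neqc of limma 3.58.1 in R 4.3.3, with the background inferred from the detection p-values and an offset of 16. A probe entered a comparison when its detection p was under 0.01 on at least 3 arrays of the fit. Where several probes shared a symbol, the one with the highest mean over all arrays stood for the gene. In the siRNA comparisons, 2858 genes in OE21 and 2779 in OE33 had several detected probes. With 1 probe called in OE21 and 0 in OE33, called probes could not disagree there. Of these genes, 535 in OE21 and 172 in OE33 had a probe at an unadjusted p under 0.05, and 4 and 0 of them had such probes in both directions. Between the control cells of the lines, 34 of 3271 genes with several probes had called probes in both directions.

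The siRNA comparison was fitted separately in each line (6 arrays, 4 residual degrees of freedom). The difference between the lines' siRNA effects and the difference between their control cells came from 1 fit of all 12 arrays (8 residual degrees of freedom). Tests were two-sided moderated tests of lmFit and eBayes with Benjamini-Hochberg adjustment, and genes with adjusted p under 0.05 are called. Fold changes are on the log2 scale with standard errors (SE). A probe detected on 0 arrays of a group gives only a bound, computed against the lowest detected signal of each array and written as at least N-fold. A gene detected on 0 arrays of a group has no value given for the difference between the lines' effects. With 3 arrays against 3, an exact permutation test cannot give p below 0.1, and the number of arrays limits the precision.

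The 30 gene lists covered STAT and cytokine signalling, textbook STAT3 targets, interferon, inflammation, cell cycle, cell death, squamous and columnar epithelium, metabolism, stress and other cell types. Lists with at least 5 measured genes were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were the alternatives. The list of IL-6 family receptors and JAK-STAT components is called IL-6 family genes for short, and not all its members serve IL-6 family cytokines. In OE21 the estimated correlation was -0.008 for STAT3 targets and -0.011 for IL-6 family genes, below the preset one. For these 2 lists a larger p with the estimated correlation therefore does not by itself show correlated genes. The other passing lists in OE21 had estimates above the preset one. Among them were interferon-stimulated genes (0.749), S phase genes (0.789), antigen presentation (0.508) and mitosis (0.266). For such lists the p at the preset correlation assumes less correlation than was estimated. Fry asks whether a list's genes move one way on balance and does not compare them with other genes.

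Named genes followed 1 rule. For each siRNA comparison these were STAT3, the up to 10 passing genes per direction with the largest change whose arrays did not overlap, filled to 5 per direction by smallest unadjusted p where fewer passed, and the 4 members with the smallest p of each passing list. The 4 members with the smallest p of the STAT3 target and IL-6 family lists were named in any case. For the difference between the lines' effects, the same 4 members of passing lists were named. Between control cells, the 8 largest differences per direction and the leading members of the squamous and columnar lists were named. Genes with the same direction in both lines were taken by the larger of their p-values, up to 10. Y-linked genes, XIST and LOC identifiers were not named.

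The functions were tested on simulated arrays with the real genes' means and residual spreads, independent noise and 50 genes at each fold. In the OE21 comparison (11179 genes), 6% of genes changed 1.5-fold, 44% of genes changed 2-fold, 76% of genes changed 4-fold and 96% of genes changed 8-fold were recovered. In the OE33 comparison (10634 genes), the shares were 18%, 60%, 88% and 100%. For the difference between the lines' effects (12322 genes) they were 2%, 26%, 78% and 92%, and for the control cells (12322 genes) 22%, 40%, 92% and 100%. The simulation did not include the shared shifts of whole arrays seen in the real data. The changed genes of all folds were in the same run, with 118 calls in OE21, and more calls ease the Benjamini-Hochberg threshold. The shares may therefore be too high for a comparison in which few genes change. Alternatives changed the background correction, normalisation, probe filter, choice of probes, arrays in the fit, variance model, array weights, replicate block, left-out replicates and thresholds. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.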

Results

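The series measured gene expression in OE21 cells, an esophageal squamous cell carcinoma line, and OE33 cells, a line from a Barrett's adenocarcinoma, after transfection with siRNA against STAT3. STAT3 is a transcription factor activated by IL-6 family cytokines. Each line had 3 arrays of cells given the STAT3 siRNA and 3 of cells given a control siRNA. Between 18034 and 19149 probes per array were detected, 38.1% to 40.5% of all probes. Arrays correlated at 0.968 to 0.989 across probes within either line and at 0.841 to 0.876 between the lines. Correlations across probes describe these arrays, since genes are not independent replicates.

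STAT3 was the target, and its level was read first. In OE21, mean STAT3 intensity was 9.12 ± 0.19 (SD, n = 3) log2 units in control cells, and 6.76, 6.77 and 7.47 on the siRNA arrays. The log2 fold change was -2.12 (SE 0.23), leaving 22.9% of the control level (95% confidence interval 15.7% to 33.5%). It was smaller in size with no background correction (-1.52) and in the authors' values (-1.54), both outside this interval. All 3 siRNA arrays lay below all 3 control arrays, and no gene tested had a smaller p or a larger fall. The limma adjusted p was 0.278 over all 11179 genes and 0.000214 adjusted over the list alone, that of the STAT family. The other STAT3 probes gave -2.00 each. In a fit of all 12 arrays the limma adjusted p was 0.0222, and with array weights 0.0264, and over all alternatives it ranged from 0.0222 to 0.781.

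In OE33, STAT3 was 9.55 ± 0.63 (SD, n = 3) in control cells and 9.01 ± 0.12 (SD, n = 3) after the siRNA. The log2 fold change was -0.55 (SE 0.30), leaving 68.4% (95% confidence interval 42.1% to 111%), with limma adjusted p = 0.991 over all genes and 0.541 adjusted over the list alone. The other STAT3 probes gave -0.28 and -0.55, and in the latter all 3 siRNA arrays lay below the control arrays. Without control 2, whose STAT3 level was the highest, the value was -0.19, and the other probes gave -0.05 and -0.43. The siRNA effect on STAT3 was weaker in OE33 than in OE21 by 1.58 log2 units (SE 0.41), with limma adjusted p = 0.0112 adjusted over the list alone and 0.574 over all genes.

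**Figure D1:**
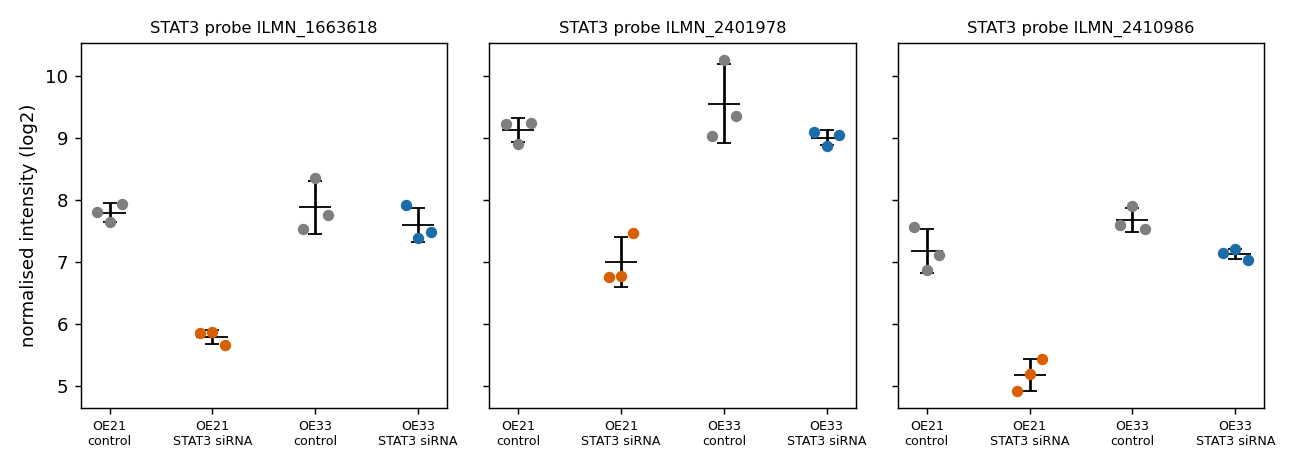
Normalised log2 intensity of the 3 STAT3 probes on each array (points), by cell line and siRNA, with the group mean (bar) and SD (whiskers), n = 3 arrays per group. In OE21 the siRNA arrays lie about 2 log2 units below the control arrays on every probe, and in OE33 the log2 fold changes of the probes are -0.28, -0.55 and -0.55.

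The OE21 comparison asked which genes follow the reduction of STAT3 in squamous carcinoma cells. Interferon-stimulated genes were higher after the siRNA, with all 49 measured members above the control mean and a median log2 fold change of 0.56 (adjusted p = 3.52e-16, and adjusted p = 0.452 with an estimated correlation). Their mean level overlapped between the groups, at 0.06 log2 units from the line's mean on control 1 and -0.04 on siRNA 3. The members with the smallest p were CXCL10, a chemokine induced by interferon (1.53, SE 0.30), ISG20, an antiviral exonuclease (1.46, SE 0.26), OASL (1.23, SE 0.27) and GBP1, a guanylate-binding protein (1.13, SE 0.28). Genes of mitosis were lower, 44 of 47 below the control mean with a median of -0.30 (adjusted p = 1.22e-10, and adjusted p = 0.399 with an estimated correlation), among them BUB1 (-0.64), CDC25C (-0.61), CKS2 (-0.59) and the kinase AURKA (-0.58).

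No single gene passed in OE21. Limma called 0 of 11179 genes, against 1259 at an unadjusted p under 0.05, where 559 were due by chance. Leaving out single arrays gave from 681 (without siRNA 1) to 1965 (without siRNA 3). Another split of these arrays, control 1, siRNA 1 and siRNA 2 against the rest, gave 3541 at that threshold. The 3 siRNA arrays lay all above or all below the control arrays for 1888 genes (16.9%, where chance gives 10%). The smallest unadjusted p-values among genes that were lower belonged to STAT3, MAEA (-1.28, SE 0.14), DENR, a translation reinitiation factor (-1.27, SE 0.15), the insulin-degrading enzyme IDE (-0.89, SE 0.12) and C8orf33 (-1.26, SE 0.18). Among genes that were higher they belonged to AGFG1 (1.09, SE 0.16), the adhesion molecule ALCAM (1.01, SE 0.15), LINGO2 (0.99, SE 0.15), cytidine deaminase CDA (at least 1.96-fold) and CHRNA2 (at least 1.94-fold). The limma adjusted p-values of these genes were 0.278 or 0.300, and CDA and CHRNA2 were detected on 0 of 3 control arrays. In a fit of all 12 arrays 17 genes were called, and with array weights 270, STAT3 among them in both. The OE21 weights were lowest for siRNA 3 (0.360) and control 1 (0.468). These arrays lie across the siRNA label in the split above, so the 270 calls may follow that split. Tested as single probes, 1 probe passed, which was of STAT3.

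Of 28 lists tested in OE21, 12 passed camera at the preset correlation, 8 higher and 4 lower, and 0 passed with an estimated correlation. Other splits of these arrays, across the siRNA label and taken after seeing the data, passed 5 to 9 lists. Over all genes 0 members of any list were called in the main fit. With array weights 13 interferon-stimulated genes were called higher and 0 lower, and some members of other lists were also called. Adjusted over the list alone, 3 interferon-stimulated genes and 0 mitosis genes passed. The mean interferon level differed among the OE21 control arrays, at 0.06, -0.75 and -0.30 log2 units from the line's mean, and was 0.51, 0.52 and -0.04 on the siRNA arrays.

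Inflammatory genes were also higher in OE21. Of 22 measured NF-kB and cytokine genes 19 lay above the control mean, with a median of 0.44 (adjusted p = 2.45e-05, and adjusted p = 0.311 with an estimated correlation). The chemokines CXCL1 (1.49) and CCL5 (0.94) and the IkB protein NFKBIZ (0.59) passed when adjusted over the list alone, and lymphotoxin beta LTB was at 1.06. The mean level of this list lay at -0.62 on control 1 and 0.68 on siRNA 3. Antigen presentation genes had a median of 0.30 (adjusted p = 0.00112, and adjusted p = 0.499 with an estimated correlation), led by the peptide transporters TAP1 (0.71) and TAP2 (0.46), the transactivator NLRC5 (0.85) and TAPBP (0.57). LTB and NLRC5 were detected on 1 of 3 control arrays. The mean level of the antigen presentation list lay at 0.10, 0.32 and 0.31 on control 1, siRNA 1 and siRNA 2, and at -0.31, -0.28 and -0.14 on control 2, control 3 and siRNA 3. With these sets of arrays as a block, chosen after seeing the data, its median was 0.10 (adjusted p = 0.0146). The antigen presentation median was 0.17 without control 2, 0.20 without siRNA 1, 0.16 without siRNA 2 and 0.52 without siRNA 3, and the list passed each time. The list of IL-6 family receptors and JAK-STAT components had a median of 0.21 (adjusted p = 0.00357, and adjusted p = 0.304 with an estimated correlation), with IL22RA1 at 0.72, IL10RB at 0.70, PIAS3 at 0.38 and SOCS4 at 0.37.

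Textbook STAT3 targets, which active STAT3 is known to induce, were not lower in OE21. Of 36 measured targets 25 lay above the control mean, with a median of 0.17 (adjusted p = 0.00931, and adjusted p = 0.304 with an estimated correlation). The estimated correlation of this list was -0.008, below the preset one. The 4 members with the smallest p were IRF1 (0.54), TWIST1 (0.59), SERPINB3 (0.96) and the receptor subunit IL6ST (1.07), and 0 passed adjusted over the list alone. The call was lost without control 1, at a median of 0.20 (adjusted p = 0.077), and without siRNA 3, at 0.21 (adjusted p = 0.151). The list's mean level lay at -0.23 on control 1 and 0.24 on siRNA 3, from the mean of the line.

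Genes of S phase and DNA replication had a median of -0.24 in OE21, 38 of 41 below the control mean (adjusted p = 0.00028, and adjusted p = 0.652 with an estimated correlation), with E2F1 at -0.54, CDC6 at -0.61, POLA1 at -0.46 and CHAF1B at -0.41. Their mean level lay at -0.23 on control 1, -0.23 on siRNA 1 and -0.40 on siRNA 2, and at 0.32 on control 2, 0.28 on control 3 and 0.26 on siRNA 3. Without siRNA 2 the median was -0.10 (adjusted p = 0.0701). The list passed at -0.45 without control 1, -0.11 without control 2, -0.14 without control 3 and -0.41 without siRNA 3. With these sets of arrays as a block, chosen after seeing the data, the median was -0.03 (adjusted p = 0.243). Under the same block the cornified envelope (0.36) and the respiratory chain (-0.12) passed. Heat shock and oxidative stress genes had a median of -0.23 (adjusted p = 0.00028, and adjusted p = 0.304 with an estimated correlation). In that list the cystine transporter SLC7A11 (-0.95) passed adjusted over the list alone, SRXN1 was at -0.84 and DNAJB1 at -0.36, while heme oxygenase HMOX1 was at 0.95. Respiratory chain genes had a median of -0.06 (adjusted p = 0.0417, and adjusted p = 0.662 with an estimated correlation), with NDUFC2 at 0.74, UQCRB at -0.37, NDUFB6 at -0.29 and NDUFS3 at -0.26. NDUFC2 was detected on 1 of 3 control arrays. The mean level of this list was 0.02 on siRNA 2 and -0.03 on control 2. The respiratory chain median was -0.03 without control 1 (adjusted p = 0.517) and -0.06 without siRNA 3 (adjusted p = 0.345), and the list passed at -0.10 without control 2 and -0.11 without siRNA 2. With the replicate number as a block the call of this list was lost.

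Hypoxia and glycolysis genes had a median of 0.13 in OE21 (adjusted p = 0.00723, and adjusted p = 0.499 with an estimated correlation), with PFKFB4 at 0.68, P4HA2 at 0.54, ENO2 at 1.19 and NDRG1 at 0.78. Their mean level lay at 0.13, 0.23 and 0.33 on control 1, siRNA 1 and siRNA 2, and at -0.25, -0.28 and -0.15 on control 2, control 3 and siRNA 3. With these sets as a block the median was 0.08 (adjusted p = 0.0353). Cornified envelope genes had a median of 0.20 (adjusted p = 0.00723, and adjusted p = 0.555 with an estimated correlation), with KRT1 at 0.80, SERPINB3 at 0.96, GRHL1 at 0.67 and KLK10 at 0.56. KRT1 and GRHL1 were detected on 2 of 3 control arrays. The mean level of the cornified list was 0.25 on control 2, against -0.12, 0.06 and 0.39 on the siRNA arrays. Mesenchymal genes had a median of 0.18 (adjusted p = 0.00833, and adjusted p = 0.311 with an estimated correlation). In that list the fibronectin receptor subunit ITGA5 (1.35) passed adjusted over the list alone, and TWIST1 (0.59), SERPINE2 (0.69) and TNC (0.40) did not. Its mean level was 0.04 on control 2 and 0.03 on siRNA 2. The hypoxia median was 0.09 without control 2 (adjusted p = 0.0637) and 0.11 without siRNA 2 (adjusted p = 0.0706), and the list passed at 0.23 without siRNA 3. The cornified envelope median was 0.17 without control 1 (adjusted p = 0.102), 0.10 without control 3 (adjusted p = 0.0609) and 0.14 without siRNA 3 (adjusted p = 0.41). That list passed at 0.51 without control 2 and 0.35 without siRNA 1. The mesenchymal median was 0.18 without control 1 (adjusted p = 0.102) and 0.31 without siRNA 3 (adjusted p = 0.0599), and the list passed at 0.31 without control 2.

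**Figure D2:**
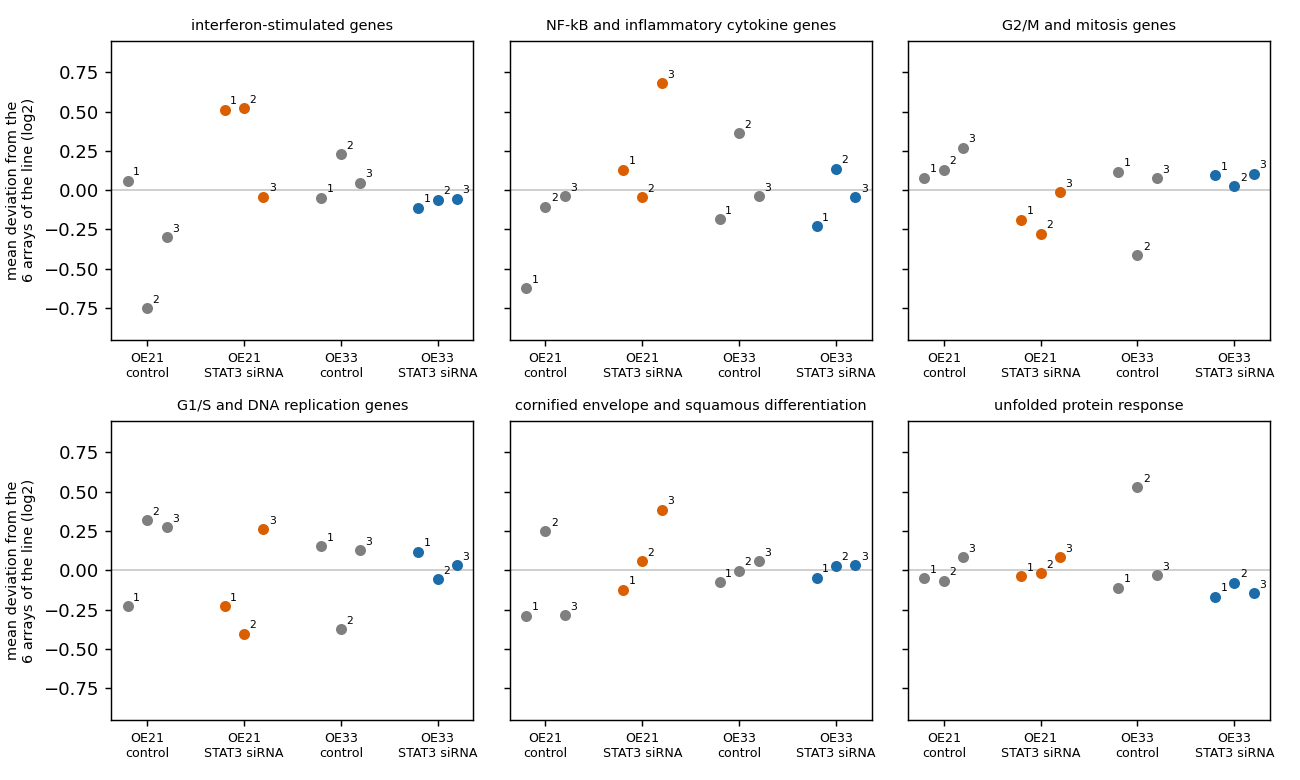
Mean log2 deviation of 6 gene lists on each array from the mean of the 6 arrays of its line, by group, with replicate numbers beside the points. In OE21 the interferon-stimulated genes lie at 0.51 and 0.52 on siRNA arrays 1 and 2 and at -0.75 on control 2, and in OE33 control 2 lies apart for the unfolded protein response (0.53) and for mitosis (-0.41).

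The 6 OE21 arrays also differed in a way that the siRNA label did not follow. The first principal component, with 52.4% of the variance, had control 1 and siRNA 1 and 2 on one side (0.34, 0.36 and 0.51) and control 2, control 3 and siRNA 3 on the other (-0.36, -0.42 and -0.42). In OE33 the first component, with 56.6%, set control 2 (-0.89) apart from the other arrays.

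**Figure D3:**
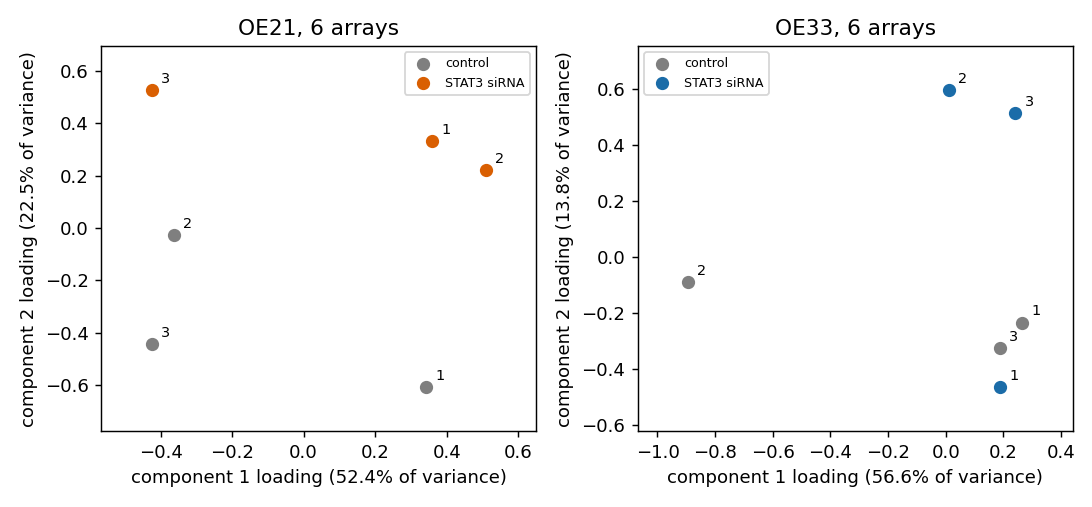
Loadings of the 6 arrays of each line on the first and second principal components of log2 intensity, centred by gene, with replicate numbers. In OE21 the first component (52.4% of variance) places control 1 beside siRNA 1 and 2, and in OE33 (56.6%) it sets control 2 at -0.89.

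The OE33 comparison asked the same of adenocarcinoma cells. Unfolded protein response genes were lower after the siRNA, 35 of 36 below the control mean with a median of -0.21 (adjusted p = 0.661 with an estimated correlation), or -0.03 without control 2 (adjusted p = 0.670). Among them were the chaperone partner DNAJC3 (-0.79), the serine synthesis enzyme PHGDH (-0.65), ATF6 (-0.30) and XBP1 (-0.29). Mitosis genes were higher, 39 of 47 above the control mean with a median of 0.15 (adjusted p = 0.661 with an estimated correlation), or -0.03 without control 2 (adjusted p = 0.886). Among them were KIF11 (0.53), BUB1B (0.36), NDC80 (0.34) and ANLN (0.31). Interferon-stimulated genes had a median of -0.15 (adjusted p = 0.661 with an estimated correlation), or -0.06 without control 2 (adjusted p = 0.258), with USP18 at -0.58, IRF7 at -0.58, MX1 at -0.42 and OASL at -0.39. Ribosomal protein genes had a median of 0.04 (adjusted p = 0.661 with an estimated correlation), with RPL7 at 0.27, RPS21 at 0.21, RPS4X at 0.20 and RPL30 at 0.19.

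These were the 4 of 29 lists that passed camera in OE33, with adjusted p of 2.08e-05, 0.00104, 0.00231 and 0.0115 in that order, and each had adjusted p = 0.661 with an estimated correlation. Other splits of the OE33 arrays, taken after seeing the data, passed 2 to 6 lists. Control 2 alone lay at 0.53 for the unfolded protein response and at -0.41 for mitosis, and without it 1 list passed, which was not among these 4. The ribosomal list had adjusted p = 0.264 without control 2 and 0.122 without siRNA 3. Its median was 0.04 in both cases. Without control 1, 7 lists passed, among them the unfolded protein response at -0.32 and mitosis at 0.28, and mitosis passed at 0.23 without control 3. STAT3 targets (median -0.09) and IL-6 family genes (median 0.03) did not pass. The members with the smallest p were CCND1 (-0.33), CEBPD (-0.40), TNFRSF1A (-0.22) and S100A9 (-0.22) of the first, and PTPN2 (0.39), SOCS7 (-0.38), SOCS5 (0.40) and SOCS1 (-0.42) of the second.

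Limma called 0 of 10634 genes in OE33, and 0 in a fit of all 12 arrays or with array weights. At an unadjusted p under 0.05 there were 292, where chance gives 532 and another split of the arrays gave up to 862. That count was 523 without control 2 and 191 without siRNA 3. The groups were separated for 7.72% of genes, where chance gives 10%. The genes with the smallest p had limma adjusted p = 0.991. Among those that were lower were C17orf75 (at least 1.86-fold), the chemokine CCL20 (-0.76, SE 0.14), MED18 (-0.75, SE 0.15), CTAGE15 (at least 1.81-fold) and the transcription factor BACH2 (-0.77, SE 0.18). Among those that were higher were FKBP1B (at least 1.61-fold), OGN (at least 2.18-fold), CPNE2 (at least 1.57-fold), HPN-AS1 (at least 1.65-fold) and EXOG (0.74, SE 0.15). MED18 and BACH2 were detected on 1 of 3 siRNA arrays, and EXOG on 1 of 3 control arrays.

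Whether the siRNA effect differed between the lines was tested directly. Interferon-stimulated genes had a lower siRNA effect in OE33 than in OE21, 48 of 49 with a difference below 0 and a median of -0.68. Adjusted over the list alone, 12 of them passed, led by ISG20 (-1.90), OASL (-1.62), IRF7 (-1.51) and CXCL10, which was detected on 0 OE33 siRNA arrays and has no difference given. Mitosis genes had a higher effect in OE33, 47 of 47 above 0 with a median of 0.52, with BUB1 at 0.78, CKS2 at 0.76, BUB1B at 0.66 and AURKA at 0.61. Camera gave adjusted p = 7.63e-21 and 1.75e-14 for these lists, and adjusted p = 0.230 with an estimated correlation for both. Limma called 0 of 12322 genes for this difference, with 829 at an unadjusted p under 0.05, where other splits gave up to 2593, and 229 called with array weights. Leaving out single arrays gave from 580 (without OE33 siRNA 3) to 1325 (without OE21 siRNA 3) at that unadjusted threshold. Without OE33 control 2 the mitosis median was 0.31, and the list passed.

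In all, 13 of 29 lists passed camera for the difference between the lines, and 0 with an estimated correlation. Other splits, with siRNA labels moved within each line after seeing the data, passed 1 to 13 lists. NF-kB and cytokine genes had a median of -0.51 (adjusted p = 0.230 with an estimated correlation), with CCL20 at -1.16, LTB at -1.20, CCL5 at -0.93 and NFKBIA at -0.55. Antigen presentation genes had -0.30 (adjusted p = 0.416 with an estimated correlation), with NLRC5 at -1.22, TAP1 at -0.89, TAPBP at -0.80 and TAP2 at -0.48. S phase genes had 0.35 (adjusted p = 0.534 with an estimated correlation), with UNG at 0.84, GINS4 at 0.63, RFC4 at 0.61 and PCNA at 0.55. Unfolded protein response genes had -0.26 (adjusted p = 0.454 with an estimated correlation), with WARS1 at -1.03, HSPA5 at -0.79, CEBPB at -0.46 and XBP1 at -0.44. Adjusted over the list alone, CCL20, TAP1 and HSPA5 passed. Without OE33 control 2 the median of the unfolded protein response was -0.09 (adjusted p = 0.322) and that of S phase 0.15 (adjusted p = 0.0641). The S phase list passed at 0.23 without OE21 control 2, 0.22 without OE21 control 3 and 0.14 without OE21 siRNA 2. Antigen presentation passed at -0.46 without OE21 control 1, -0.15 without OE21 siRNA 2 and -0.49 without OE21 siRNA 3.

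STAT3 targets had a median of -0.24 for the difference between the lines (adjusted p = 0.230 with an estimated correlation), with IRF1 at -0.64. Mesenchymal genes had -0.26 (adjusted p = 0.230 with an estimated correlation), with ITGA5 at -1.52 and SERPINE2 at -0.67. Cornified envelope genes had -0.25 (adjusted p = 0.454 with an estimated correlation), and -0.077 both with no background correction and in the authors' values, where the list passed. For mesenchymal genes those settings gave -0.14 and -0.16, and the list passed. Over the genes detected in every group, a filter chosen after seeing the data, neither call held. The cornified envelope median was 0.0034 over 27 of 44 genes (adjusted p = 0.342, with the test pointing lower), and the mesenchymal median -0.22 over 16 of 27 (adjusted p = 0.0677). The lists of heat shock and oxidative stress (0.20), ribosomal proteins (0.11), respiratory chain (0.09) and leukocyte markers (-0.38) also passed at the preset correlation. Their values were adjusted p = 0.230, 0.230, 0.463 and 0.379 with an estimated correlation. The members with the smallest p were HMOX1 (-0.91), HSPE1 (0.65), SRXN1 (0.65) and HSPA1A (0.48), RPL7 (0.59), RPS7 (0.53), RPL14 (0.44) and RPL5 (0.29), ATP5F1C (0.63), UQCRB (0.65), NDUFC2 (-0.78) and ATP5PB (0.32), and CD68 (-0.56). The other members with the smallest p lay at background in a group and have no difference given. TWIST1, SERPINB3, KRT1, S100A12 and LYZ were detected on 0 OE33 arrays, S100A8, CALML3, ZNF750 and SNAI2 on 0 OE33 siRNA arrays, and CD79A and HBB on 0 OE21 control arrays. Of the 7 measured genes on the leukocyte marker list, which includes the haemoglobin gene HBB, 2 were detected in every group, too few to test. In these 7 lists ITGA5 alone passed adjusted over the list alone.

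Calls in this last group of lists were lost when 1 array was left out, with smaller medians in some cases and equal or larger ones in others. For STAT3 targets the median was -0.18 without OE21 siRNA 3 (adjusted p = 0.0659), and the list passed at -0.16 without OE21 control 1. For the respiratory chain it was 0.07 without OE21 control 1 (adjusted p = 0.121) and 0.07 without OE21 siRNA 3 (adjusted p = 0.0814). Mesenchymal genes had medians of -0.15 without OE21 control 1 (adjusted p = 0.115), -0.17 without OE21 siRNA 3 (adjusted p = 0.0612), -0.37 without OE33 control 1 (adjusted p = 0.0606) and -0.21 without OE33 siRNA 1 (adjusted p = 0.0728). Cornified envelope genes had -0.14 without OE21 control 1 (adjusted p = 0.121), -0.14 without OE21 control 3 (adjusted p = 0.125), -0.13 without OE21 siRNA 3 (adjusted p = 0.38) and -0.13 without OE33 control 3 (adjusted p = 0.0709), and passed at -0.43 without OE21 control 2. For heat shock genes, leaving out OE21 arrays gave medians of 0.16 without control 3 (adjusted p = 0.161), 0.17 without siRNA 1 (adjusted p = 0.0878) and 0.23 without siRNA 3 (adjusted p = 0.0612). Leaving out OE33 arrays gave 0.14 without control 1 (adjusted p = 0.15), 0.17 without control 3 (adjusted p = 0.0709), 0.20 without siRNA 1 (adjusted p = 0.057) and 0.17 without siRNA 2 (adjusted p = 0.0733). For leukocyte markers, leaving out OE21 arrays gave medians of -0.45 without control 1 (adjusted p = 0.0721), -0.35 without control 3 (adjusted p = 0.115) and -0.13 without siRNA 2 (adjusted p = 0.168), and the list passed at -0.61 without siRNA 3. Leaving out OE33 arrays gave -0.33 without control 1 (adjusted p = 0.0916), -0.32 without control 3 (adjusted p = 0.139), -0.42 without siRNA 1 (adjusted p = 0.0936) and -0.40 without siRNA 2 (adjusted p = 0.0539). Ribosomal proteins passed at 0.05 without OE33 control 2 and 0.07 without OE33 siRNA 3. The leukocyte median was -0.11 with no background correction (adjusted p = 0.0663) and -0.12 in the authors' values (adjusted p = 0.0703).

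No gene was called in both lines, which compares nothing, since 0 genes were called in either line. At an unadjusted p under 0.05, 31 of 9823 genes tested in both were shared in either direction, against 25.4 due by chance (two-sided Fisher's exact test, p = 0.241). Of the 31, 20 had the same direction in both lines. Across genes, which are not independent, the fold changes of the lines correlated at 0.04. The same-direction genes with the smallest p in both were PWWP2A, PRKCA, TRIM2, MED14, RNU6-1 and RALGPS1, higher in both, and PPP6R1, RNF138, SSR3 and COG8, lower in both. TRIM2 was at 1.14 in OE21 and 0.45 in OE33, and PWWP2A at 0.61 and 0.85.

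The control cells of OE33 and OE21, which also differ in transfection reagent, were compared. OE33 had higher columnar epithelial genes, 21 of 24 measured, with a median of 1.64. The list holds 54 genes, 48 of them with a probe. Within OE33 22 of its genes passed the detection filter, and within OE21 13. Members that entered only through their higher line raise such counts by construction. Keratins KRT8 (at least 170-fold) and KRT7 (114-fold), the tight junction protein CLDN3 (6.08 log2 units) and the intestinal transcription factor CDX2 (at least 8.04-fold) had the smallest p in this list. OE21 had higher squamous keratins and desmosomal genes, 19 of 23 measured, with a median of -1.42 for OE33 minus OE21. Of these, 23 passed the detection filter within OE21 and 16 within OE33. The columnar and squamous medians were smaller in size with no background correction and in the authors' values. KRT5 was at least 294-fold, KRT6C at least 204-fold, KRT14 at least 99.6-fold and the plakophilin PKP1 at least 50.8-fold lower in OE33.

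Limma called 6060 of 12322 genes between the control cells, 3080 higher and 2980 lower in OE33, 3091 of them by at least 2-fold. The largest differences upward were KRT8, the metalloproteinase MMP7 (160-fold), CMTM7 (159-fold), ACSL5 (150-fold), GSTO2 (at least 132-fold), PLAAT3 (127-fold), the trypsinogen PRSS3 (at least 105-fold) and KRT7. Downward they were KRT5, KRT6C, ETFB (at least 151-fold), glutathione peroxidase GPX2 (183-fold), DKK3 (179-fold), ACKR3 (at least 137-fold), AKR1B10 (144-fold) and the elafin gene PI3 (115-fold). The limma adjusted p of these genes was at most 3.99e-07. The dimmer line was detected on only 1 or 2 of 3 arrays for MMP7, CMTM7, ACSL5, KRT7, CLDN3, GPX2, DKK3, AKR1B10 and PI3.

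The columnar list passed camera in control cells (adjusted p = 1.87e-06) and also with an estimated correlation (adjusted p = 0.011), the one list to do so in any comparison. Of its members 18 were called higher and 1 lower over all genes, and 19 and 1 adjusted over the list alone. Among the 18 was CEACAM5, detected on 0 control arrays of either line. The squamous keratin list passed at 0.000363, and had adjusted p = 0.666 with an estimated correlation. Of its members 2 were called higher and 13 lower in OE33, over all genes and adjusted over the list alone. Cornified envelope genes passed at 8.49e-05 with a median of -1.66 (-1.54 with undetected genes at their bounds or at 0), and adjusted p = 0.547 with an estimated correlation. In that list CSTA (at least 12.1-fold lower), S100A8 (-6.29), CALML3 (-5.54) and S100A9 (-4.28) had the smallest p, and 27 members were called lower and 9 higher, or 29 and 9 adjusted over the list alone. S100A8 and CALML3 were detected on 1 of 3 OE33 control arrays. Of the cornified envelope genes, 42 passed the detection filter within OE21 and 26 within OE33.

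**Figure D4:**
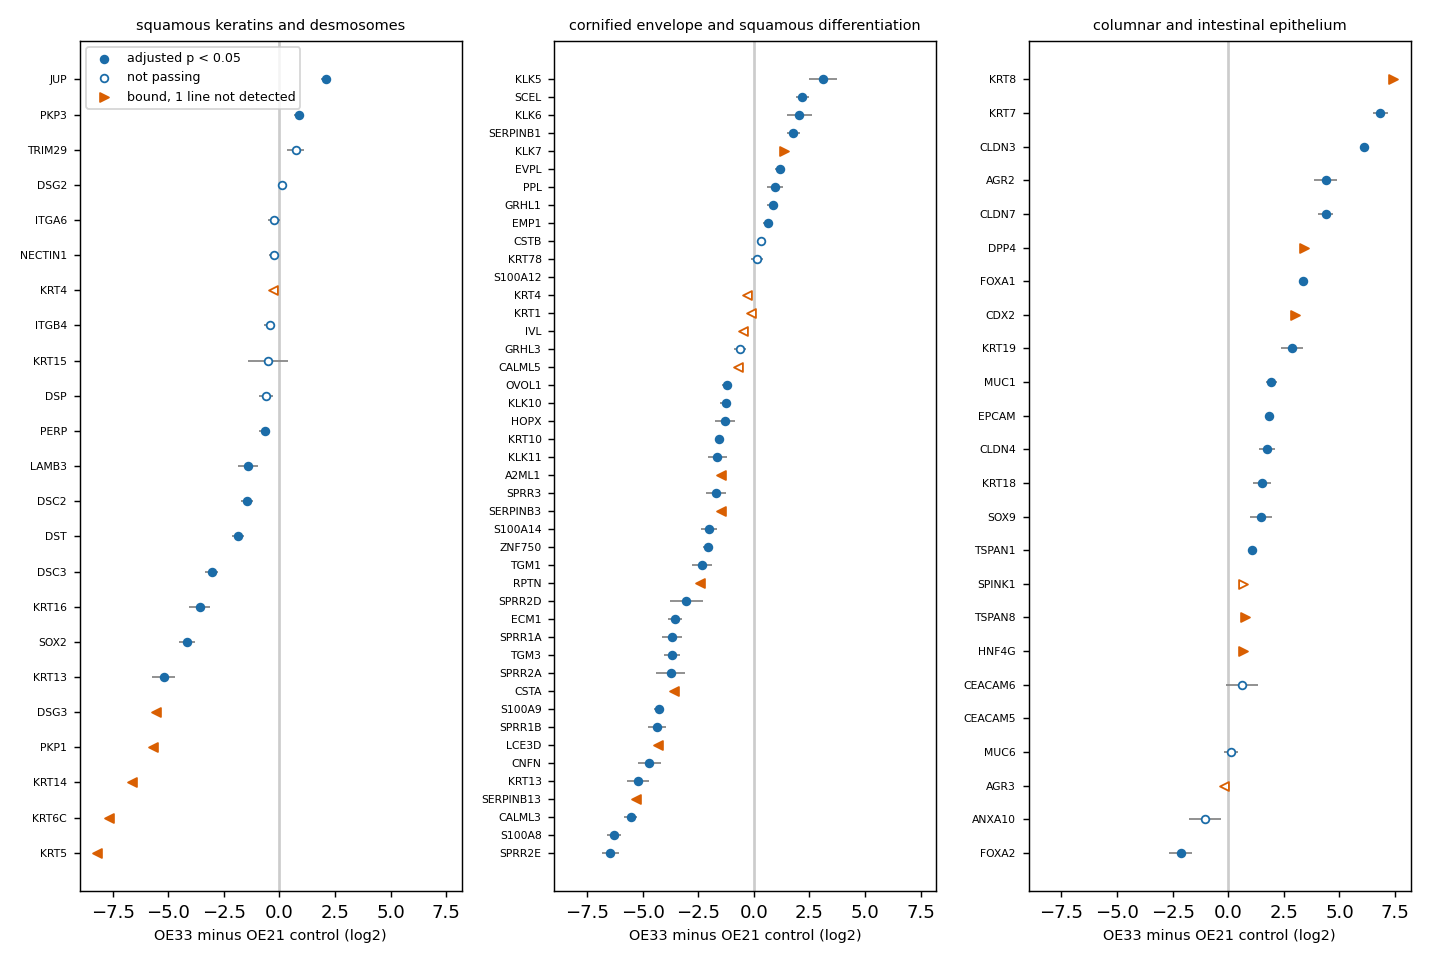
Log2 difference (OE33 minus OE21 control cells) of each measured gene of 3 epithelial lists, with SE bars from the fit of 12 arrays; filled symbols passed at adjusted p under 0.05, triangles mark genes detected on 0 control arrays of 1 line at their bound, and S100A12 and CEACAM5, with no bound, have no symbol. KRT8 (at least 170-fold) and KRT5 (at least 294-fold) lie at opposite ends, and 9 cornified envelope genes were called higher in OE33.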

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

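The tests of explanations, the other splits of the arrays, the block by array sets, the filter on genes detected in every group and the lists without single arrays in this part were chosen only after the results were seen.

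The siRNA effect on STAT3 was weaker in OE33 than in OE21 by 1.58 log2 units, and OE33 cells kept 68.4% of the control level. Leaving out control 2, the highest control, gave -0.19, which tests no explanation, since it could only shrink the fall. The STAT3 probes can report a fall, since the smallest in OE21 was -2.00. The cell line and the transfection reagent remain open and cannot be told apart here, because each line had its own reagent, and either may set how much siRNA acted.

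Interferon-stimulated genes differed between the lines by a median of -0.68 (adjusted p = 0.230 with an estimated correlation), with a median of 0.56 in OE21 (adjusted p = 0.452 with an estimated correlation) and -0.15 in OE33 (adjusted p = 0.661 with an estimated correlation). In OE21 the mean difference of the list was 0.66 (95% confidence interval -0.17 to 1.49), and with the array sets as a block 0.47 (95% confidence interval -0.04 to 0.98), so the sets may carry part of it. In OE33 the mean difference was -0.15 (95% confidence interval -0.38 to 0.08). A response to the siRNA pool itself in OE21, or to lower STAT3, cannot be told apart, because every OE21 array with lower STAT3 received the same pool. The OE33 arrays cannot settle it, because line, reagent and remaining STAT3 differ together. Of the 10 splits of the OE21 arrays, 2, counting the real one, gave a median at least as large in size as the real 0.56. The highest other gave 0.66.

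The OE21 arrays fell into 2 sets across the siRNA label, with control 1, siRNA 1 and siRNA 2 in one. That split, the one the first principal component shows, called 1508 genes where the real one called 0, which describes a structure of the samples and is no separate test of it. A swap of control 1 and siRNA 3 is argued against by STAT3, which was 1.76 log2 units higher in control 1. The normalisation used here is argued against by the authors' values, in which the same split called 2122 genes. The labels give no batch for these arrays, so a shared culture or processing day may lie behind the sets and was not tested, and no biological explanation was tested.

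Other gene lists also passed camera for the difference between the siRNA effects at the preset correlation, and 0 did with an estimated correlation (smallest adjusted p 0.230). The median differences were 0.52 for mitosis, 0.35 for S phase, 0.20 for heat shock and oxidative stress, 0.11 for ribosomal proteins and 0.092 for the respiratory chain. They were -0.51 for NF-kB and cytokine genes, -0.38 for leukocyte markers (-0.11 with no background correction and -0.12 in the authors' values, where the call was lost), -0.30 for antigen presentation, -0.26 for the unfolded protein response, -0.26 for mesenchymal genes, -0.25 for the cornified envelope and -0.24 for STAT3 targets. Over the genes detected in every group the cornified envelope median was 0.0034 (adjusted p = 0.342) and the mesenchymal median -0.22 (adjusted p = 0.0677), and 2 leukocyte genes remained, too few to test. Calls were lost without OE33 control 2 for S phase (median 0.15) and the unfolded protein response (-0.09), and without OE21 siRNA 3 for STAT3 targets (-0.18), the respiratory chain (0.07), mesenchymal genes (-0.17), the cornified envelope (-0.13) and heat shock (0.23). Without OE21 control 1 they were lost for the respiratory chain (0.07), mesenchymal genes (-0.15), the cornified envelope (-0.14) and leukocyte markers (-0.45), and without OE21 control 3 for the cornified envelope (-0.14), heat shock (0.16) and leukocyte markers (-0.35). Heat shock lost its call without OE21 siRNA 1 (0.17), and leukocyte markers without OE21 siRNA 2 (-0.13). Without OE33 control 1 the calls of mesenchymal genes (-0.37), heat shock (0.14) and leukocyte markers (-0.33) were lost, and without OE33 control 3 those of the cornified envelope (-0.13), heat shock (0.17) and leukocyte markers (-0.32). Without OE33 siRNA 1 those of mesenchymal genes (-0.21), heat shock (0.20) and leukocyte markers (-0.42) were lost, and without OE33 siRNA 2 those of heat shock (0.17) and leukocyte markers (-0.40). The mitosis median was 0.31 without OE33 control 2, and the list passed.

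Among probes without a gene symbol, which enter no comparison of genes, 1361 of 5239 were called between the control cells of the lines.

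For the difference between the lines' effects, 100 splits were taken, the real one included. A real count of 0 genes is met by all 100 by construction (highest other 496), so the count of genes tests nothing. For the count of lists, 3 of 100, counting the real split itself, gave at least the real 13 (others 1 to 13), a share under 0.05. Moving labels within each line removes any siRNA effect, shared or not. The share therefore sets the real count against no effect in either line, and does not by itself test whether the lines' effects differ.

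In the other comparisons 3 arrays against 3 make 10 splits, the real one included, too few for a share under 0.05. For genes, the real count of 0 in OE21 (highest other 1508) and in OE33 (highest other 0) is met by all 10 by construction and tests nothing. In OE21 only the real split reached its 12 lists (others 5 to 9). In OE33 4 splits, the real one included, gave at least the real 4 lists (others 2 to 6). Between control cells only the real split reached its 6060 genes (highest other 0). Every other split there puts arrays of both lines in each group, which widens the spread, so their low count is largely fixed by construction. For lists between control cells, 2 splits, the real one included, gave at least the real 9 (others 5 to 9).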

How the results depend on the processing

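Leaving out single arrays or undetected genes for the gene lists, all 12 arrays or the authors' values for the lists, and the block by array sets were chosen after seeing the data. The cause of each change below was not tested. In OE21, 1 probe was called when every probe was tested, 17 genes (8 higher, 9 lower) in a fit of all 12 arrays and 270 (174 higher, 96 lower) with array weights. All 17 were among the 270. For the difference between the lines' effects, array weights called 229 genes (71 higher, 158 lower). The STAT3 log2 fold change in OE21 was -2.12 in the fit of all 12 arrays (adjusted p = 0.0222) and -2.29 with array weights (adjusted p = 0.0264). Between control cells, 3091 genes passed with at least a 2-fold change, fewer by construction. Array weights were highest for OE21 siRNA 1 (3.86) and OE33 control 3 (4.27), and lowest for OE33 control 2 (0.147). Within OE21 they were lowest for siRNA 3 (0.360) and control 1 (0.468). These arrays lie across the siRNA label in the array sets, so calls made with array weights may follow those sets.

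With an estimated correlation 0 gene lists passed in OE21, 0 in OE33, 0 for the difference between the lines and 1 between control cells. With fry the counts were 0, 0, 0 and 18. Leaving out each array in turn, 10 to 13 lists passed in OE21, 1 to 7 in OE33, 10 to 15 for the difference and 6 to 11 between control cells. With no background correction several passing lists had medians smaller by over 1.5 times: between control cells 0.98 for columnar, -0.76 for squamous keratin, -0.79 for cornified envelope and -0.40 for mesenchymal genes, for the difference -0.077 for cornified envelope and -0.14 for mesenchymal genes, and in OE21 0.13 for IL-6 family and 0.11 for STAT3 target genes. In the authors' values they were 1.00, -0.80, -0.82 and -0.42 between control cells. Over genes detected in every group compared, 12 lists passed in OE21, 4 in OE33, 10 for the difference and 12 between control cells, where the squamous keratin median was -0.62 and the mesenchymal -0.46, since the filter removes genes absent from 1 line. The mitosis list in OE33 ranged from -0.030 without control 2, where its direction turned, to 0.28 without control 1. With single arrays left out, genes called numbered 0 in both lines and for the difference, and 5375 to 6256 between control cells. In the same fits, with single arrays left out, STAT3 ranged from -2.36 to -2.00 in OE21 (adjusted p from 0.0732 to 0.781) and from -0.80 to -0.19 in OE33. With all arrays of each line and no background correction it was -1.52 in OE21 and -0.48 in OE33. In the authors' values it was -1.54 and -0.48.

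With the replicate number as a block, 0 genes were called in OE21, 0 in OE33 and 0 for the difference. The block left 11 lists passing in OE21, where the respiratory chain had adjusted p = 0.0698. Deviations of same-numbered arrays correlated at 0.33, -0.30 and 0.39 in OE21 and at 0.06, 0.22 and 0.08 in OE33. In each line 1 of 3 numbers matched best with itself. These values do not show that the numbers pair the arrays, and with 3 arrays per group they cannot exclude it.

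Across settings, values of named genes kept direction and side of the threshold in 873 of 910 cases in OE21, with 37 newly past it, in 572 of 572 in OE33, in 903 of 918 for the difference and in 408 of 408 between control cells. Apart from STAT3, the named genes were chosen by p or size of change in the same data, so these counts are no separate test. In OE33 no gene was called in any setting, so the kept side of the threshold tests nothing there. Probes near background limit the folds given as bounds.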

Other observations

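No test in this part was chosen after its result was seen, except the lists without single arrays and in the authors' values. Control cells of OE33 had lower interferon-stimulated genes than those of OE21, with a median of -2.03, 39 of 49 called lower and 1 higher over all genes, and 41 and 1 adjusted over the list alone. Camera gave adjusted p = 9.08e-13, and adjusted p = 0.611 with an estimated correlation. Heat shock and oxidative stress genes had a median of -0.49 (adjusted p = 0.00187, and adjusted p = 0.09 with an estimated correlation), and mesenchymal genes -0.77 (adjusted p = 0.00949, and adjusted p = 0.09 with an estimated correlation), or -0.40 with no background correction and -0.42 in the authors' values.

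Mitosis genes had a median of -0.37 in OE33 against OE21 control cells (adjusted p = 0.0289, and adjusted p = 0.846 with an estimated correlation), and -0.37 without OE21 control 3 (adjusted p = 0.0729) and -0.28 without OE33 control 2 (adjusted p = 0.213). Epithelial adhesion genes had 0.66 (adjusted p = 0.045, and adjusted p = 0.654 with an estimated correlation), and respiratory chain genes -0.30 (adjusted p = 0.045, and adjusted p = 0.753 with an estimated correlation). The adhesion median was 0.71 without OE21 control 2 (adjusted p = 0.0627), 0.55 without OE21 control 3 (adjusted p = 0.0539) and 0.31 without OE33 control 2 (adjusted p = 0.104), and the list passed at 1.01 without OE33 control 1. It was 0.66 without OE21 siRNA 3, OE33 siRNA 2 or OE33 siRNA 3, with adjusted p = 0.0504, 0.0504 and 0.0502. The respiratory chain median was -0.26 without OE21 control 1 (adjusted p = 0.13) and -0.25 without OE33 control 2 (adjusted p = 0.117). It was -0.30 without OE21 siRNA 2, OE21 siRNA 3, OE33 siRNA 2 or OE33 siRNA 3, with adjusted p = 0.0528, 0.055, 0.0504 and 0.0502.

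The remaining lists passed in neither line after the siRNA. Their medians in OE21 and OE33 were 0.63 and 0.16 for acute phase proteins, 0.34 and 0.09 for matrix metalloproteinases and the plasminogen system, and 0.25 and -0.16 for squamous keratins and desmosomes. They were 0.17 and -0.01 for EGFR and ERBB ligands and receptors, 0.14 and -0.06 for epithelial adhesion, 0.13 and -0.05 for immediate-early genes, and 0.12 and -0.01 for cholesterol biosynthesis. For p53 targets they were 0.08 and -0.09, for the RNA interference machinery 0.04 and -0.04, and for columnar epithelium 0.02 and 0.13. Anti-apoptotic genes had camera adjusted p = 0.989 and 0.858, pro-apoptotic genes 0.264 and 0.938, and CDK inhibitors and G1 cyclins 0.978 and 0.398. In OE21 alone, the unfolded protein response (median 0.05) and ribosomal proteins (-0.02) did not pass. The STAT family had a median of 0.01 and a mean of -0.42 in OE21, which differ in sign, and a median of -0.09 in OE33. Fibroblast and endothelial markers had 3 measured genes in OE21 and 1 in OE33, too few to test, and leukocyte markers 3 in OE21, too few to test, and a median of -0.12 in OE33.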
